A study of Rattus norvegicus with 6 samples.

How the data were processed

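Total RNA from the livers of 6 male rats, 3 given corn oil and 3 given CCl4, was labelled with Cy3 from 0.2 µg and hybridised to 1-colour Agilent rat arrays, per the labels' protocols. The labels describe the replicates of a group as separate animals. Groups were taken from the treatment label, and the replicate numbers from the titles. The deposited scanner files hold intensity values per spot, read with Agilent Feature Extraction (version 10.7 in the submitters' processing notes, 10.7.1.1 per the file headers), which subtracted background but did not scale arrays to each other. Other columns used are flags for spots well above background, saturated or outlying, per the file headers. The deposited value table holds a linear ratio, in constant proportion to the processed signal of each array with a spread of at most 0.044%. The divisor that this implies was 583.3 to 676.5 units per array, near the array's 75th percentile of 582.6 to 675.6. Column medians of the ratio were 0.103 to 0.110. The labels do not describe that scaling step, so it was inferred from the values.

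Of 61537 probes other than the 1439 control spots, 28193 (45.8%) matched 1 gene symbol through the unversioned RefSeq accession given in the files, in a gene table of the GRCr8 assembly, and 33344 matched none. The array's design names the older rn4 build, so no coordinates are given. This covered 15639 symbols. Control spots were left out, as were 26 probes with an outlier flag on any array. Each probe had a single spot, so no spots were averaged. Signals were log2-transformed and each array's 75th percentile was subtracted. Genes were tested when a probe was well above background on at least 3 of the 6 arrays, and the probe with the highest mean stood for a gene with several, which left 11933 genes. Of the 76 changed genes 24 had several probes, and in 2 these disagreed in sign. The precision is limited by the number of arrays, 3 per group, and between 0 and 4 probes per array were saturated.

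The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Where no array of a group was well above background, the fold is a bound: the bright group's mean over all its arrays was set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Gene lists were tested with camera at its preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 29 lists, and the members of each list were also adjusted over the list alone. The 29 lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls among changed genes well above background on all 6 arrays with groups that did not overlap, up to 3 genes per direction with the largest bound, up to 2 changed members per direction of each list, and 18 fixed genes whatever their result. Other list members are examples chosen after their values were seen. Some genes that the rule chose are not reported here.

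The test was checked on simulated data for this comparison, with 11933 genes and 20 runs of 200 changed genes each. It recovered 61.3% of genes changed by 1 on the log2 scale, 88.0% at 2 and 95.0% at 3, and 5.9% of its calls were false. The simulated errors were normal with each gene's own SD, independent between genes and without a slide effect. These rates therefore do not cover the slide layout of these arrays or an outlying animal. The camera test gave an unadjusted p below 0.05 in 1.5% of 200 unchanged sets, with genes drawn independently, so this does not test the preset correlation.

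The alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the authors' values, no filter and a filter on all 6 arrays, the mean of a gene's probes, a variance trend, array weights, a 2-fold minimum, slide as a fixed or random block, the first slide alone, the replicate number as a block, and leaving out each array. The normexp alternative used median spot signals (gMedianSignal) instead of the planned mean signals, which are not among the columns of the files used here. Analyses also used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0.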

Results

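Liver RNA was measured on 1-colour microarrays in 6 male Sprague-Dawley rats, an outbred laboratory stock, that were 5 weeks old when purchased. Of these, 3 rats received corn oil, the vehicle, and 3 received carbon tetrachloride (CCl4) at 100 mg/kg/day, and each rat gave 1 array. CCl4 is a solvent that the cytochrome P450 enzyme CYP2E1 converts to reactive products, and it is used to produce liver injury and fibrosis in rodents. The labels disagree on exposure: the series design places the measurement at 28 days, whereas the treatment protocol gives 9 weeks of dosing, and the files do not settle which is right. The 75th percentile of the processed signal was 582.6 to 675.6 units per array, and 61.9% to 67.3% of the 61537 probes were well above background. Arrays correlated at 0.984 to 0.990 within a group and at 0.973 to 0.987 between groups across the genes tested, which are not independent replicates. The first principal component held 43.4% of the variance and separated the groups, with scores of -38.63 to -13.66 for corn oil and 13.73 to 35.32 for CCl4. The first slide held the 3 corn oil arrays and CCl4 replicate 1, and the second slide, scanned on another day, held CCl4 replicates 2 and 3. A fit with slide as a block therefore rests its CCl4 estimate on CCl4 replicate 1, and its fold changes equal those within the first slide. Values within the first slide set 1 CCl4 array against 3 and do not show that a difference holds across animals.

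The comparison of CCl4 with corn oil asks which liver genes differ after repeated exposure to the chemical. Macrophage genes, chemokines and cell division genes were among the genes that rose in CCl4 livers, and the iron hormone hepcidin and several metabolic enzymes were among those that fell. Trem2, a lipid-sensing receptor of macrophages, rose 20.1-fold (log2 change 4.33 ± 0.32, SE, n = 3 arrays per group; adjusted p = 0.0106). Hamp, which encodes hepcidin, fell by 2.12 ± 0.21 on the log2 scale (adjusted p = 0.0252). Of 11933 genes tested, 76 changed at an adjusted p below 0.05, 67 of them higher and 9 lower in CCl4, and 64 changed at least 2-fold. At an unadjusted p below 0.05 there were 2354 genes, 1188 higher and 1166 lower, where chance gives 597. The groups did not overlap for 3266 genes (27.4%, against 10% by chance), which included all 76 changed genes. With slide as a fixed block 4 genes passed, and within the first slide limma called 0, with 1598 genes at an unadjusted p below 0.05. The count was 27 without corn oil replicate 1, 43 without corn oil replicate 2, 5 without corn oil replicate 3, 6 without CCl4 replicate 1, 2 without CCl4 replicate 2 and 241 without CCl4 replicate 3.

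The genes with the largest rises among those well above background on every array came from several functions. Il23a, which encodes a subunit of an inflammatory cytokine, rose 20.1-fold (4.33 ± 0.47; adjusted p = 0.0252). Nol3, an apoptosis repressor, rose 13.0-fold (3.71 ± 0.39; adjusted p = 0.0252). Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages, rose 8.20-fold (3.04 ± 0.42; adjusted p = 0.0462), and Lilrb4, an inhibitory receptor of myeloid cells, rose 7.93-fold (2.99 ± 0.26; adjusted p = 0.0171). Slc1a6, a glutamate transporter best known from neurons, rose 7.84-fold and had the smallest adjusted p of all genes (2.97 ± 0.11; adjusted p = 0.00132). Msantd3 rose 7.73-fold (2.95 ± 0.41; adjusted p = 0.0462), and Derl3, a component of endoplasmic reticulum-associated degradation, rose 7.27-fold (2.86 ± 0.32; adjusted p = 0.0252). For 8 of the genes that rose, no corn oil array was well above background, so only a bound on the fold can be given. Mmp12, the macrophage metalloelastase, was at least 36.1-fold higher (adjusted p = 0.0171), the matrix glycoprotein gene Tnn at least 15-fold higher (adjusted p = 0.00154) and the germ cell gene Tex15 at least 5.11-fold higher (adjusted p = 0.0252), each well above background on 3 CCl4 arrays. These bounds hold for the processed signal: normexp background correction, which adds an offset and so shrinks changes of dim genes, gave log2 changes of 2.86 for Mmp12, 1.75 for Tnn and 0.86 for Tex15, which no longer passed (adjusted p = 0.0800). Under normexp the rises of Il23a (2.45), Trem2 (2.74), Lilrb4 (1.41), Slc1a6 (1.63) and Msantd3 (1.78) were smaller too, and passed.

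Among the 9 genes that fell, Hamp was bright in both groups, at 7.75 ± 0.37 in corn oil and 5.64 ± 0.20 in CCl4 (log2 relative to each array's 75th percentile, SD, n = 3). Fmo1, a flavin monooxygenase that oxidises drugs, fell by 1.44 ± 0.17 (adjusted p = 0.0256), and Gzma, a protease of cytotoxic T and natural killer cells, fell by 1.32 ± 0.14 (adjusted p = 0.0252). Insig2, which retains sterol-regulated transcription factors in the endoplasmic reticulum, fell by 0.89 ± 0.10 (adjusted p = 0.0256). Rundc3b fell by 1.66 ± 0.21 (adjusted p = 0.0330) and Tbc1d24 by 1.17 ± 0.13 (adjusted p = 0.0252). C7h12orf54 was not well above background on any CCl4 array and was at least 2.10-fold lower (adjusted p = 0.0252). Under normexp, C7h12orf54 (-0.40, adjusted p = 0.138) and Rundc3b (-0.84, adjusted p = 0.0564) did not pass, and Tbc1d24 was at -0.71. All 25 genes past the threshold that the naming rule chose had the same sign with slide as a fixed block, where Tnn (5.77), Slc1a6 (2.99) and Rrm2 (2.74) passed, each with adjusted p = 0.0458. Of the others, Il23a came nearest (5.28, adjusted p = 0.0873), while Trem2 (4.06, adjusted p = 0.136), Hamp (-2.09, adjusted p = 0.195) and Gpnmb (2.43, adjusted p = 0.239) did not pass. For these 25 genes the groups did not overlap, so the sign could not turn in a fit that rests on CCl4 replicate 1. Of these 25 genes, 9 passed without corn oil replicate 1, 14 without corn oil replicate 2, 3 without corn oil replicate 3, 4 without CCl4 replicate 1, 2 without CCl4 replicate 2 and 23 without CCl4 replicate 3.

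**Figure D1:**
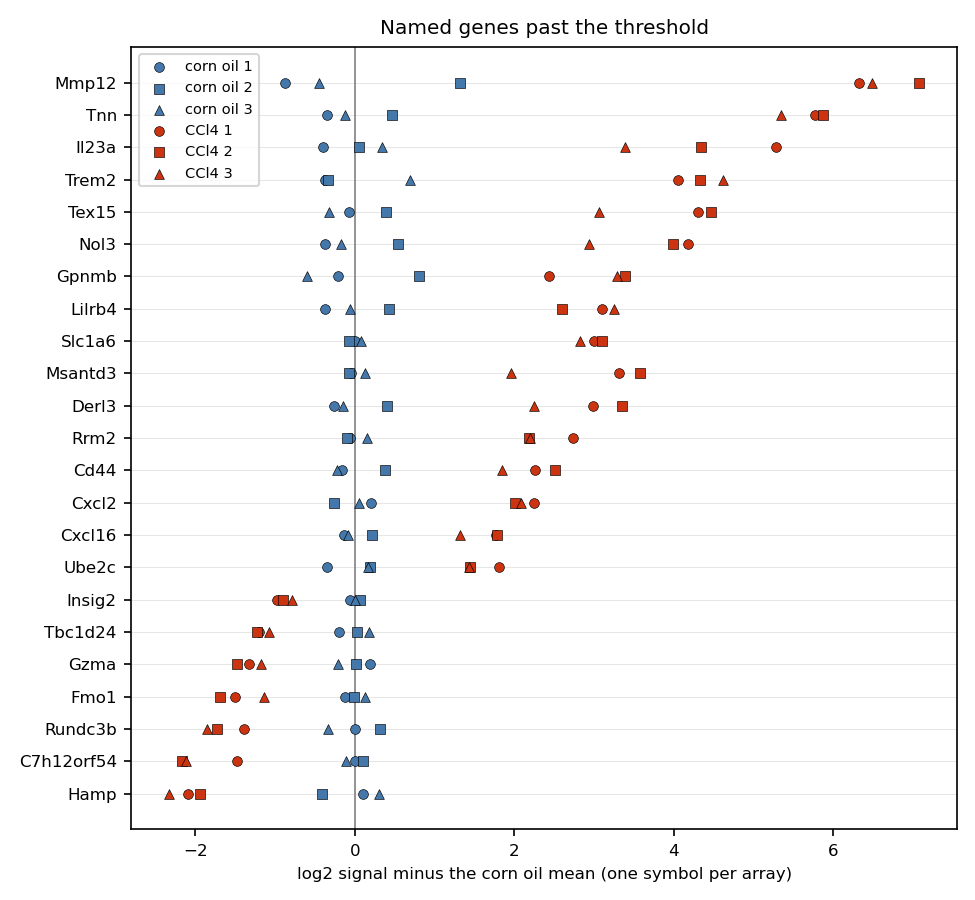
Log2 signal of each array minus the corn oil mean (x axis) for genes past the threshold (y axis), with 1 symbol per array, blue for corn oil and red for CCl4. The groups do not overlap for any of these genes, and the widest separation is that of Mmp12, whose corn oil arrays were not well above background.

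Of 29 gene lists, 19 passed limma's camera test, which sets a list's shift against that of all other genes, 10 of them higher and 9 lower in CCl4. With a correlation between genes estimated from these arrays, 0 of the 29 passed, and the smallest adjusted p was 0.298. Lists that passed are given below with the adjusted p under both, and for the 10 that did not the adjusted p with an estimated correlation was 0.577 to 0.840. All are given with the median log2 change and the number of members that passed when adjusted over the list alone. With slide as a block, members passed over the list alone in the cell cycle (24 higher), macrophage (5 higher), matrix (4 higher), fetal and focus marker (4 higher), cytokine (2 higher), lipogenesis (2 higher, 1 lower), lymphocyte, pericentral, acute phase and other tissue lists (1 lower each). In the remaining lists 0 did.

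Cell cycle genes had the largest shift. Of 42 measured members 5 rose over all genes tested, 34 were higher when adjusted over the list alone, and 41 had a positive change, with a median of 0.96 (adjusted p = 2.02e-24, and adjusted p = 0.298 with an estimated correlation). Rrm2, the regulated subunit of ribonucleotide reductase, rose 5.19-fold on its brightest probe (2.38 ± 0.18; adjusted p = 0.0114), while the lowest of its 4 probes gave 1.14. Ube2c, which marks mitotic proteins for degradation, rose 2.95-fold (1.56 ± 0.19; adjusted p = 0.0326). The mitotic genes Ccna2 (1.53 ± 0.14), Aurka (0.96 ± 0.11) and Birc5 (0.93 ± 0.13) also rose. Mki67, a marker of dividing cells, was 0.81 ± 0.17 higher without passing over all genes (adjusted p = 0.0830), but passed under normexp (0.73, adjusted p = 0.0477) and with probe means (1.14, adjusted p = 0.0450). The list's median was 1.05, 1.07 and 0.93 in the CCl4 arrays and -0.31, 0.22 and 0.17 in the corn oil arrays. With slide as a block the median was 1.05 (adjusted p = 4.45e-22, and 3.36e-18 within the first slide), with 24 members higher over the list alone and 6 within the first slide. The median was 0.57 under normexp (adjusted p = 1.36e-23), where Ube2c was at 1.00.

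**Figure D2:**
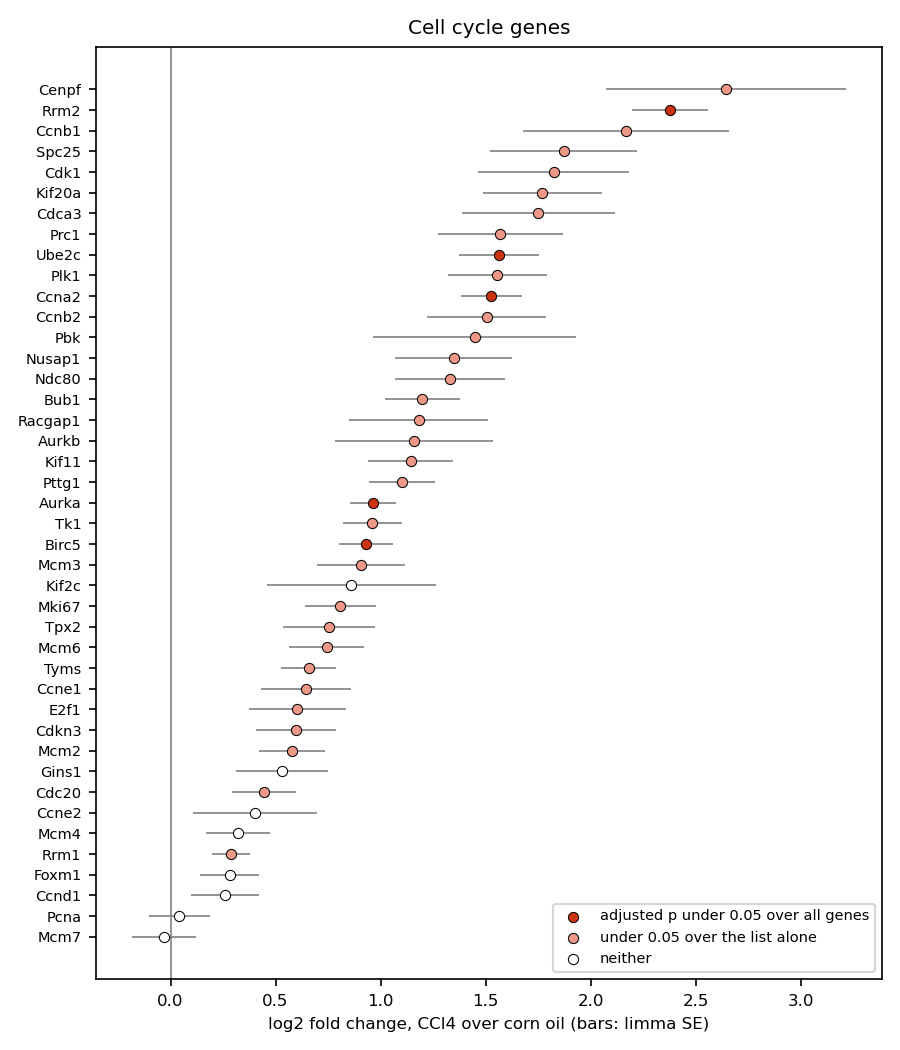
Log2 fold change of CCl4 over corn oil (x axis, bars are limma standard errors, 3 arrays per group) for the 42 measured cell cycle genes (y axis), coloured by the test each passed. All but 1 lie above 0, and Rrm2, Ube2c, Ccna2, Aurka and Birc5 passed over all genes.

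The p53 target list was higher by a median of 0.22 (adjusted p = 0.00224, and adjusted p = 0.534 with an estimated correlation), with 0 of 27 members past the threshold over all genes and 3 over the list alone, Perp (0.58 ± 0.10), Ccng1 (0.92 ± 0.17) and Tp53inp1 (0.82 ± 0.20). Cdkn1a, the cell cycle inhibitor that p53 controls, was at -0.21 ± 0.12 (adjusted p = 0.371), and its sign turned when a gene's probes were averaged (0.23). The list's median was 0.39 with slide as a block (adjusted p = 0.00101, and 0.000565 within the first slide) and 0.14 without CCl4 replicate 1. Its 3 members were 0 without corn oil replicate 1 or CCl4 replicate 1 or 2, and 8 higher and 1 lower without CCl4 replicate 3.

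Fetal and liver focus markers, genes known from liver development and altered hepatocyte foci, were higher by a median of 0.29 (adjusted p = 0.000902, and adjusted p = 0.298 with an estimated correlation). Of 23 members 1 rose over all genes and 7 were higher over the list alone. Cd44, a hyaluronan receptor, rose 4.61-fold on its brightest probe (2.21 ± 0.23; adjusted p = 0.0252), whereas its lowest probe gave 0.05. Anxa2 (1.85 ± 0.28) and the drug exporter gene Abcb1b (2.34 ± 0.37) passed over the list alone, and Gstp1, a glutathione transferase of such foci, was at 0.37 ± 0.18 (adjusted p = 0.303). Other members passed neither over all genes nor over the list. Among them were Afp (0.29 ± 0.16), Ggt1 (0.18 ± 0.48), Gpc3 (0.03 ± 0.13), Aldh3a1 (0.05 ± 0.12), Igf2 (-0.30 ± 0.28) and H19 (-0.40 ± 0.22). With slide as a block the median was 0.29 (adjusted p = 0.000881, and 0.000255 within the first slide), and the 7 members were 3 without corn oil replicate 1 or CCl4 replicate 1 and 4 without corn oil replicate 2 or 3, the latter with 1 lower.

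Of 26 macrophage markers 3 rose over all genes: Trem2, Gpnmb and Lgals3, a lectin of activated macrophages (5.15-fold, 2.36 ± 0.15; adjusted p = 0.00729). Over the list alone Lyz2 (0.95 ± 0.15), Itgam (1.99 ± 0.35), Marco (0.91 ± 0.24) and Tyrobp (0.47 ± 0.13) were also higher, and C1qc, a complement gene of resident macrophages, was lower (-0.60 ± 0.15), but 0 were lower without corn oil replicate 3 or any CCl4 array. Itgam was well above background on 2 of 3 corn oil arrays. The markers Clec4f (-0.35 ± 0.14) and Vsig4 (-0.50 ± 0.21) and the general marker Cd68 (0.13 ± 0.13, adjusted p = 0.628) did not pass. The list as a whole had a median of 0.06 and a mean of 0.47 (adjusted p = 0.0312, and adjusted p = 0.591 with an estimated correlation). Its call was lost with slide as a block (median 0.05, adjusted p = 0.273, and 0.338 within the first slide), without corn oil replicate 1 (median -0.04, adjusted p = 0.121) and without CCl4 replicate 3 (0.12, adjusted p = 0.178). It was also lost without a filter on dim probes (0.12, adjusted p = 0.0768) and with the filter on all 6 arrays (0.008, adjusted p = 0.0784). The median was 0.11 under quantile normalization, 0.03 under median scaling, 0.13 without corn oil replicate 2, 0.12 without corn oil replicate 3 and 0.15 without CCl4 replicate 1. Cd68 was at -0.018 with slide as a block.

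Cytokine and chemokine genes were higher by a median of 0.21 (adjusted p = 0.00703, and adjusted p = 0.298 with an estimated correlation), with 2 of 33 members risen over all genes. Cxcl2, a neutrophil attractant, rose 4.34-fold (2.12 ± 0.15; adjusted p = 0.0103) and was well above background on 1 of 3 corn oil arrays, with a log2 change of 0.66 under normexp, and Cxcl16 rose 3.09-fold (1.63 ± 0.18; adjusted p = 0.0252). Over the list alone 7 were higher, among them the monocyte attractant Ccl2 (1.93 ± 0.29), and Ccl5 was lower (-0.45 ± 0.09), where 0 were lower without corn oil replicate 1 and 2 without corn oil replicate 2 or CCl4 replicate 2 or 3. The list did not pass with slide as a block (median 0.06, adjusted p = 0.0722) or within the first slide (adjusted p = 0.0689), and its median was 0.31 without CCl4 replicate 1 and 0.32 without CCl4 replicate 3. Interferon and antigen presentation genes were higher by a median of 0.47 (adjusted p = 2.62e-05, and adjusted p = 0.298 with an estimated correlation), with 0 of 31 members past the threshold over all genes. The class II genes RT1-Da (0.87 ± 0.16) and Cd74 (0.79 ± 0.17) were higher over the list alone, and probes of RT1 family members may not be specific. The interferon list's median was 0.45 with slide as a block (adjusted p = 2.6e-05, and 5.74e-07 within the first slide), 0.45 and 0.44 in CCl4 replicates 1 and 2, and 0.04 in CCl4 replicate 3. Its 2 members over the list alone were 0 without corn oil replicate 1 or 3 or CCl4 replicate 2, 3 without corn oil replicate 2 or CCl4 replicate 1, and 9 without CCl4 replicate 3.

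Markers of other immune and blood cells did not pass. Lymphocyte genes had a median of -0.04 (adjusted p = 0.748), and of 29 members Gzma alone fell, over all genes and over the list, where 2 were lower without CCl4 replicate 2, 3 without CCl4 replicate 3, and 1 was higher without corn oil replicate 2. Neutrophil and mast cell genes had a median of -0.08 (14 members, adjusted p = 0.728), with 0 past the threshold over the list alone and 1 higher without CCl4 replicate 1. Erythroid genes had a median of -0.03 and a mean of 0.09, in a test pointing higher (10 members, adjusted p = 0.445), with 0 past the threshold, but the list passed without CCl4 replicate 2 (0.46, adjusted p = 0.0182). Blocked by slide, these medians were -0.03 (adjusted p = 0.579), -0.15 (adjusted p = 0.272) and 0.19 (adjusted p = 0.229).

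Extracellular matrix genes were higher by a median of 0.41 (adjusted p = 1.2e-05, and adjusted p = 0.564 with an estimated correlation). Of 39 members Mmp12 alone rose over all genes, while 10 were higher and 1 lower over the list alone. These included the collagen genes Col15a1 (1.11 ± 0.19), Col1a2 (0.99 ± 0.18) and Col3a1 (0.73 ± 0.20) and the fibrillin gene Fbn1 (1.23 ± 0.21), with the microfibril gene Mfap5 lower (-0.95 ± 0.22), although 0 were lower without corn oil replicate 2 or 3 or CCl4 replicate 2. Timp1, a metalloproteinase inhibitor of scarring liver, was at 1.22 ± 0.21 (adjusted p = 0.0647), and passed over the list alone. Over all genes, Timp1 passed under normexp (1.30, adjusted p = 0.0267), with the filter on all 6 arrays (adjusted p = 0.0498) and with a variance trend (adjusted p = 0.0428). Col1a1 was at 0.16 ± 0.26 on its brightest probe (adjusted p = 0.760), at -0.07 without CCl4 replicate 1 and at 1.09 when its probes were averaged. Tgfb1 was at 0.20 ± 0.17 (adjusted p = 0.533). The matrix list's median was 0.63 and 0.50 in CCl4 replicates 1 and 2 but -0.00 in CCl4 replicate 3, and it was 0.63 with slide as a block (adjusted p = 7.24e-09, and 1.01e-09 within the first slide). The median was 0.19 under normexp (adjusted p = 2.84e-06) and 0.23 without CCl4 replicate 1, and the 10 higher members were 6 without corn oil replicate 3 or CCl4 replicate 1 or 2 and 19 without CCl4 replicate 3.

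Stellate cell and myofibroblast markers were higher by a median of 0.09 (adjusted p = 0.0322, and adjusted p = 0.591 with an estimated correlation). Of 26 members 0 passed over all genes, and over the list alone Vim was higher (0.66 ± 0.14) and Ecm1, an extracellular matrix protein gene, lower (-0.56 ± 0.11). Acta2, which encodes the smooth muscle actin of myofibroblasts, was at -0.24 ± 0.16 (adjusted p = 0.438), and at 0.02 with slide as a block. The list's call was lost without corn oil replicate 1 (median 0.16, adjusted p = 0.0995), corn oil replicate 3 (0.09, adjusted p = 0.0991), CCl4 replicate 1 (0.05, adjusted p = 0.154) or CCl4 replicate 2 (0.02, adjusted p = 0.125), under quantile normalization (0.07, adjusted p = 0.0572), without a filter (0.07, adjusted p = 0.183) and with probe means (0.08, adjusted p = 0.0889). Neither Vim nor Ecm1 passed over the list without corn oil replicate 1 or 3 or CCl4 replicate 1 or 2. In that list 0 members were lower without corn oil replicate 2, and 6 were higher without CCl4 replicate 3. The stellate median was 0.20 without corn oil replicate 2, 0.29 without CCl4 replicate 3, and 0.20 with slide as a block (adjusted p = 0.0105, and 0.00195 within the first slide). Endothelial markers had a median of 0.08 (21 members, adjusted p = 0.398), and -0.16 with slide as a block (adjusted p = 0.311), but they passed without corn oil replicate 3 (0.17, adjusted p = 0.0270), and 0 members passed over the list alone. Cholangiocyte markers had a median of -0.06 and a mean of 0.07, in a test pointing higher (20 members, adjusted p = 0.639). Of these, Anxa5 (0.61 ± 0.11) was higher over the list alone, where 0 members passed without corn oil replicate 1 or 3 or CCl4 replicate 1 or 2 and 2 without either other array. Krt19, a bile duct keratin, was at -0.17 (adjusted p = 0.565). Markers of other tissues had a median of 0.01 (12 members, adjusted p = 0.644), with 0 past the threshold over the list alone. In that list 2 were higher and 1 lower without corn oil replicate 1, and 1 was higher without CCl4 replicate 1. Blocked by slide, the cholangiocyte median was -0.13 (adjusted p = 0.80) and that of other tissues 0.23 (adjusted p = 0.905).

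Hepatocyte function genes were lower by a median of -0.30, with 39 of 44 members negative (adjusted p = 2e-04, and adjusted p = 0.591 with an estimated correlation), yet 0 passed over all genes or over the list alone. Alb was at -0.21 ± 0.14 (adjusted p = 0.434). The hepatocyte median was -0.30 with slide as a block (adjusted p = 0.00101, and 0.000255 within the first slide), and -0.48 in CCl4 replicate 2 against -0.08 in CCl4 replicate 3. Quantile normalization gave -0.18 (adjusted p = 0.0416). Xenobiotic P450 genes were lower by a median of -0.28 and a mean of -0.11 (adjusted p = 0.0212, and adjusted p = 0.577 with an estimated correlation), with 0 of 31 past the threshold over all genes. Over the list alone 5 were lower, among them Cyp3a2 (-1.65 ± 0.32) and Cyp2d4 (-0.75 ± 0.16), and Cyp2c24 (3.98 ± 0.72) and Cyp2c22 (0.96 ± 0.20) were higher. Cyp2e1, whose product activates CCl4, was at -0.41 ± 0.23 (adjusted p = 0.370), Cyp1a2 at -1.08 ± 0.23 (adjusted p = 0.0868), Cyp2b1 at -0.53 ± 0.15 (adjusted p = 0.139) and the male-specific Cyp2c11 at -1.27 ± 0.51 (adjusted p = 0.244). Without CCl4 replicate 3, Cyp2c11 passed (-1.87, adjusted p = 0.0279). Close paralogs of these families can share probe signal, which the files cannot resolve. The P450 call was lost without corn oil replicate 1 (median -0.24, adjusted p = 0.121) or CCl4 replicate 1 (-0.20, adjusted p = 0.0981) and under quantile normalization (-0.22, adjusted p = 0.129). Its 7 members past the list's own threshold were 0 without corn oil replicate 3, CCl4 replicate 1 or CCl4 replicate 2 and 11 without CCl4 replicate 3. The slide-blocked P450 median was -0.47 (adjusted p = 0.00188, and 0.000464 within the first slide).

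Male-predominant liver genes were all lower, 13 of 13 with a median of -0.41 (adjusted p = 0.00323, and adjusted p = 0.591 with an estimated correlation), and 0 passed over all genes and Cyp3a2 alone over the list. Their median was -0.47 with slide as a block (adjusted p = 0.00139, and 5.37e-05 within the first slide), -0.24 without CCl4 replicate 2, -0.25 under quantile normalization (adjusted p = 0.0315), and -0.03 in CCl4 replicate 3. Cyp3a2 did not pass over this list without corn oil replicate 1 or 3 or CCl4 replicate 1 or 2, and 6 members passed without CCl4 replicate 3. Female-predominant genes had a median of -0.26 but a mean of 0.22, in a test pointing lower (10 members, adjusted p = 0.395), with 0 past the threshold over the list alone. Of them 2 were higher without corn oil replicate 1 and 1 lower without CCl4 replicate 1. While 7 of the 10 members were negative, the largest rises were those of Srd5a1 (3.05 ± 2.89) and Cyp2c12 (2.57 ± 0.84, adjusted p = 0.184). Srd5a1 lay at -7.38 in corn oil replicate 3, and its other probe gave -0.35. The female-predominant median was -0.40 with slide as a block (adjusted p = 0.336).

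Pericentral genes had a median of -0.24 (adjusted p = 0.0368, and adjusted p = 0.298 with an estimated correlation), with 0 of 29 past the threshold over all genes. Adjusted over the list alone, Gstm3 was higher and 6 were lower, including the carboxylate transporter gene Slc13a3 (-1.55 ± 0.26) and the xenobiotic receptor gene Nr1i3 (-1.10 ± 0.20). The glutamine synthetase gene Glul was at -0.24 (adjusted p = 0.606). The pericentral call was lost without corn oil replicate 1 (adjusted p = 0.116), without CCl4 replicate 3 (adjusted p = 0.0554), under quantile normalization (-0.19, adjusted p = 0.0704) and with slide as a block (median -0.20, adjusted p = 0.0722, and 0.0267 within the first slide). Its 6 lower members were 1 without CCl4 replicate 2, and its 1 higher member was 0 without CCl4 replicate 1 or 2 and 2 without corn oil replicate 3 or CCl4 replicate 3. Periportal genes had a median of -0.28 (adjusted p = 0.0202, and adjusted p = 0.591 with an estimated correlation), with 0 of 23 past the threshold over all genes, and Igfals (-0.81 ± 0.15), a carrier of growth factors in blood, was lower over the list alone but in none of the 6 sets with an array left out. The periportal call was lost without corn oil replicate 1 (median -0.16, adjusted p = 0.208) or CCl4 replicate 2 (-0.18, adjusted p = 0.123) and under quantile normalization (-0.21, adjusted p = 0.0791). The periportal median was -0.32 with slide as a block (adjusted p = 0.0465, and 0.0220 within the first slide).

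Conjugating enzymes of the UGT, SULT and GST families did not pass as a list (35 members, median -0.21, adjusted p = 0.0609), but did without CCl4 replicate 1 (-0.23, adjusted p = 0.0446) or CCl4 replicate 3 (-0.22, adjusted p = 0.0383) and without a filter (-0.21, adjusted p = 0.0172). Over the list alone 8 were lower, such as Gstm7 (-0.97 ± 0.20) and Ugt2b1 (-1.32 ± 0.32), and Ugt2b7 (1.59 ± 0.24) and Gstm3 (2.24 ± 0.55) were higher. Of the 8 lower genes at most 1 passed when any array but CCl4 replicate 3 was left out. The 2 higher were 1 without corn oil replicate 1 or CCl4 replicate 1 and 0 without CCl4 replicate 2. The list's median was -0.08 with slide as a block (adjusted p = 0.207). NRF2 targets, which respond to oxidative stress, were higher by a median of 0.15 (adjusted p = 0.0321, and adjusted p = 0.591 with an estimated correlation). Of 31 members 0 passed over all genes, and 2 were higher over the list alone, the glutathione peroxidase gene Gpx2 (4.11 ± 0.80) and the exporter gene Abcc3 (2.20 ± 0.43). Nqo1 was at -0.39 (adjusted p = 0.473) and Hmox1 at -0.20 (adjusted p = 0.539), and Nqo1 was at 0.00 with slide as a block. The NRF2 call was lost without corn oil replicate 1 (median 0.05, adjusted p = 0.265) or CCl4 replicate 1 (0.08, adjusted p = 0.184) and without a filter (0.15, adjusted p = 0.173). Its median was 0.29 with slide as a block (adjusted p = 0.00223, and 0.00144 within the first slide). The 2 members were 5 without corn oil replicate 2, 4 without CCl4 replicate 3 and 0 without any of the other arrays.

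Fatty acid oxidation genes were lower by a median of -0.27, with 34 of 40 members negative (adjusted p = 0.000438, and adjusted p = 0.577 with an estimated correlation) and 0 past the threshold over all genes. Over the list alone 5 were lower, including the carnitine palmitoyltransferase gene Cpt2 (-0.55 ± 0.10) and Ech1 (-0.64 ± 0.13), and the thioesterase gene Acot1 was higher (2.05). The median was -0.24 with slide as a block (adjusted p = 0.00204, and 0.00299 within the first slide). Its 5 lower members were 0 without corn oil replicate 1 or 3 or CCl4 replicate 1 or 2. Of the higher there were 0 without corn oil replicate 1 or CCl4 replicate 1 or 2, and 2 without CCl4 replicate 3. Bile acid genes were lower by a median of -0.25 (adjusted p = 0.0312, and adjusted p = 0.298 with an estimated correlation), with 0 of 27 past the threshold over all genes. Over the list alone 5 were lower, among them Cyp8b1, the sterol 12-hydroxylase (-1.31 ± 0.25), and the sterol exporter genes Abcg5 (-1.42 ± 0.39) and Abcg8 (-2.08 ± 0.57), while Abcc3 was higher. Abcg8 was well above background on only 1 of 3 CCl4 arrays. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 1.22 ± 1.14 (adjusted p = 0.575), from 0.27 without corn oil replicate 3 to 2.40 without corn oil replicate 1, and at 2.52 with slide as a block. The bile acid call was lost with slide as a block (median -0.28, adjusted p = 0.155, and 0.180 within the first slide), without corn oil replicate 1 (-0.25, adjusted p = 0.0674), without CCl4 replicate 3 (-0.32, adjusted p = 0.0781), under quantile normalization (-0.20, adjusted p = 0.0572) and with the filter on all 6 arrays (-0.25, adjusted p = 0.0510). Its 5 lower members were 0 without corn oil replicate 1 or CCl4 replicate 1, 1 without corn oil replicate 3, 3 without corn oil replicate 2 and 8 without CCl4 replicate 3. Its 1 higher member was 0 without corn oil replicate 1 or 3 or CCl4 replicate 1, 2 without CCl4 replicate 2 and 3 without CCl4 replicate 3.

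Cholesterol synthesis genes were higher by a median of 0.13 (adjusted p = 0.0312, and adjusted p = 0.629 with an estimated correlation), with 0 of 26 members past the threshold over all genes or over the list alone, where 2 were higher without CCl4 replicate 3. The cholesterol call was lost without corn oil replicate 3 (median 0.05, adjusted p = 0.266), CCl4 replicate 1 (0.12, adjusted p = 0.181) or CCl4 replicate 2 (0.08, adjusted p = 0.116) and without a filter (0.13, adjusted p = 0.131). The cholesterol median was 0.22 without corn oil replicate 1 or 2, 0.28 without CCl4 replicate 3 and 0.29 with slide as a block (adjusted p = 0.00402, and 0.00299 within the first slide). Lipogenesis genes did not pass (25 members, median 0.10, adjusted p = 0.325), with Insig2 fallen over all genes and Acaca (0.69 ± 0.15) and Fasn (1.44 ± 0.34), which build fatty acids, higher over the list alone. The higher members were 0 without corn oil replicate 1 or CCl4 replicate 1 or 2, 1 without corn oil replicate 3 or CCl4 replicate 3 and 3 without corn oil replicate 2. The lipogenesis median was 0.19 with slide as a block (adjusted p = 0.0722).

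Acute phase genes were lower by a median of -0.30 (adjusted p = 0.00256, and adjusted p = 0.591 with an estimated correlation). Of 32 members Hamp alone fell over all genes, and over the list alone the pentraxin gene Apcs (-0.93 ± 0.19) was also lower and Lbp, which binds bacterial lipopolysaccharide, was higher (0.72 ± 0.16). The acute phase median was -0.18 with slide as a block (adjusted p = 0.0298, and 0.0262 within the first slide), and the list did not pass under quantile normalization (-0.15, adjusted p = 0.0988). Its 2 lower members were 7 without corn oil replicate 2, 6 without CCl4 replicate 3 and 1 without any of the other arrays. Its 1 higher member was 0 without corn oil replicate 1 or 3 or CCl4 replicate 2. Heat shock and metallothionein genes were lower by a median of -0.15 (adjusted p = 0.0455, and adjusted p = 0.577 with an estimated correlation), with 0 of 18 past the threshold over all genes. The chaperone genes Hsph1 (-0.51 ± 0.12), Stip1 (-0.60 ± 0.15) and Hspa8 (-0.44 ± 0.11) were lower over the list alone, and none of them in any set with an array left out. The heat shock call was lost with slide as a block (median -0.17, adjusted p = 0.273, and 0.333 within the first slide) and without corn oil replicate 2 (adjusted p = 0.112), corn oil replicate 3 (adjusted p = 0.0528) or CCl4 replicate 3 (adjusted p = 0.248). It was also lost under quantile normalization (-0.05, adjusted p = 0.228), median scaling (-0.18, adjusted p = 0.0528) and normexp (-0.11, adjusted p = 0.0831) and with the filter on all 6 arrays (-0.15, adjusted p = 0.0515). Endoplasmic reticulum stress genes did not pass (33 members, median 0.15, adjusted p = 0.127), but did without corn oil replicate 2 (0.08, adjusted p = 0.0490) or 3 (0.28, adjusted p = 0.00604), and lay at -0.014 without corn oil replicate 1. Of their members Ero1b (0.77 ± 0.14) and Ddit3 (1.02 ± 0.19) were higher over the list alone, where 0 were without CCl4 replicate 1 or 2, 1 without corn oil replicate 1 or CCl4 replicate 3 and 3 without corn oil replicate 3. Without corn oil replicate 1, 2 were lower. The list's median was 0.21 with slide as a block (adjusted p = 0.0690).

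**Figure D3:**
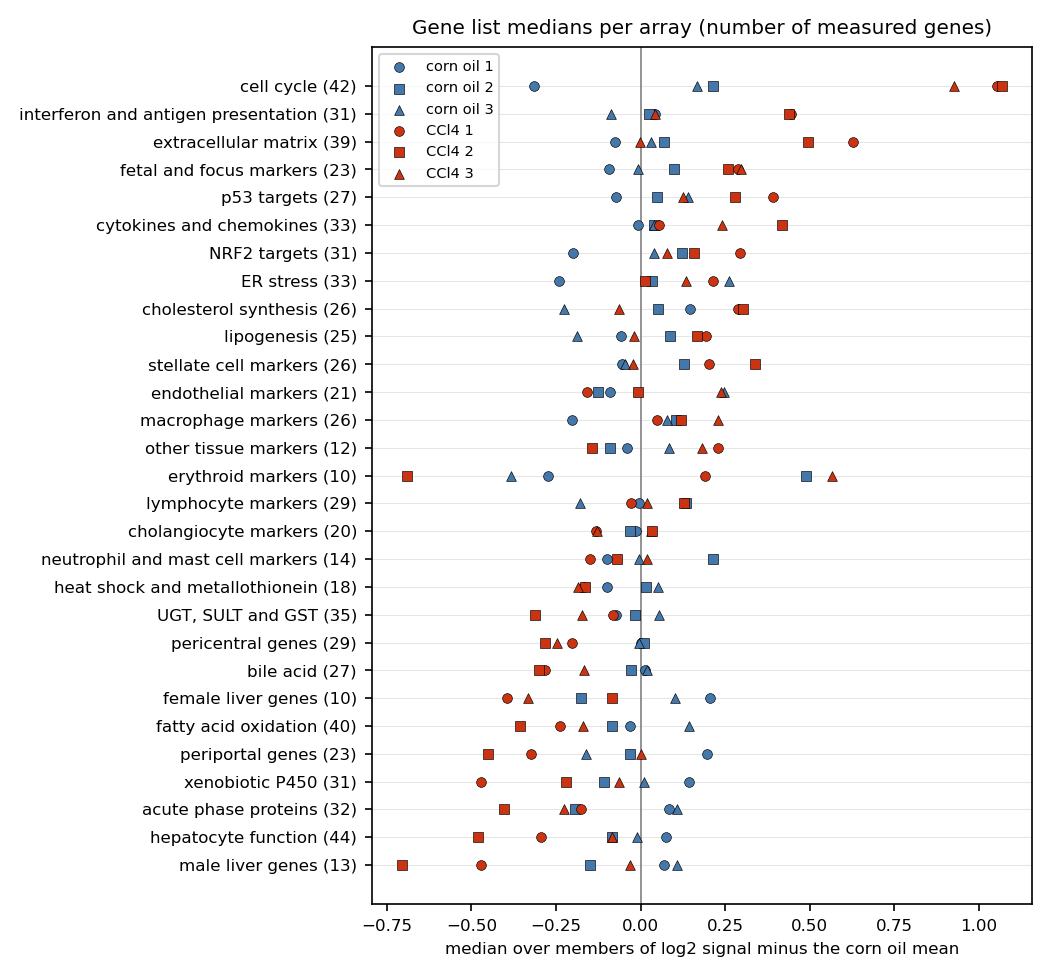
Median over each list's members of log2 signal minus the corn oil mean (x axis), for each array (blue corn oil, red CCl4, 1 symbol per replicate) and each of the 29 gene lists (y axis, measured members in parentheses). The cell cycle list separates the groups most widely (0.93 to 1.07 in CCl4, -0.31 to 0.22 in corn oil), while in the matrix and interferon lists CCl4 replicate 3 lies at -0.00 and 0.04, among the corn oil arrays.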

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

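The tests of slide, of lymphocytes and of macrophage number were chosen after the result was seen, those of slide also replaced an earlier comparison of the first slide whose outcome was known, and the tests of other splits and of the lipid-associated list before.

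Probes with no gene symbol here stood outside the comparison by gene, and 40 of 20030 tested were higher in CCl4 and 9 lower, with 2837 at an unadjusted p below 0.05 in limma. The largest rises were those of probe C_CA_A0016, by 6.35 on the log2 scale (from -0.85 to 5.50, adjusted p = 0.0133), and probe A_42_P738337, by 4.51 (from -3.13 to 1.38, adjusted p = 0.0199).

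The rise of cell cycle genes was weighed against slide and against lymphocytes. With slide as a block 24 of 42 members were still higher and past the threshold over the list alone, but that estimate rests on a single CCl4 array, 1 animal, so slide or scan day stays open. Dividing lymphocytes as a source stay open: the lymphocyte list had a median of -0.041 with an SD of 0.509 over its members, which decides nothing. The effect of CCl4 on division of liver cells, a biological difference named by the design, also stays open.

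The rise of Trem2, Gpnmb and Lgals3 was weighed against macrophage number and slide. The other 23 markers of the macrophage list had a median change of 0.008 (SD 0.629), so they did not rise together by the 2.36 or more of these 3. These 3 were picked as the largest rises of that same list, so the gap does not decide whether macrophages were more numerous. With slide as a block, Trem2 went from 4.33 ± 0.32 to 4.06 ± 0.46, Gpnmb from 3.04 ± 0.42 to 2.43 ± 0.54 and Lgals3 from 2.36 ± 0.15 to 2.39 ± 0.24. They no longer passed over all genes, with larger SEs and, for Trem2 and Gpnmb, smaller changes. Although each passed over the macrophage list (highest adjusted p = 0.0293), a single CCl4 array beside corn oil leaves slide or scan day open. A change of macrophage state may also remain, as a hypothesis.

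The 6 arrays can be split into 3 and 3 in 10 ways, so no share of splits can fall below 0.1. Every other split puts arrays of both treatments in each group. Part of any CCl4 difference then remains between the groups, and the rest adds to the spread within them. Where CCl4 differs from corn oil, such splits give few changed genes by construction, so their counts are not those of groups free of treatment. The real split gave 76 changed genes against at most 1 in any other split, 67 against 1 for the larger direction and 9 against 0 for the smaller. It gave 19 lists against 16, and 34 cell cycle members over the list alone against 0. In each case 1 split, the real one, gave as many. At the preset correlation the cell cycle list also passed camera in other splits, with medians up to 0.58, against 0.96 in the real one. Its adjusted p was as low as 7.79e-10 in those splits, against 2.02e-24.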

How the results depend on the processing

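All 76 changed genes kept their sign under every setting that tested them, 63 under the filter on all 6 arrays, and the authors' values gave the same counts of 76 genes (67 higher, 9 lower) and 19 lists. The groups did not overlap for any of these 76 genes, so leaving out arrays or blocking by slide could not turn a sign. Named genes past the threshold kept their side in 295 of 470 values and lost it in 175, with 0 reversed, and the others stayed in 327 of 342, with 6 newly past the threshold and 9 reversed. Median scaling gave 92 higher and 15 lower genes. The counts of changed, higher and lower genes were 214, 172 and 42 under normexp, 57, 48 and 9 without a filter, 140, 119 and 21 with the filter on all 6 arrays, 100, 91 and 9 with probe means, 156, 130 and 26 with a trend, 128, 112 and 16 with array weights, 105, 94 and 11 with slide as a random block (consensus correlation -0.039), 4, 4 and 0 with slide as a fixed block, and 0, 0 and 0 within the first slide. Without 1 array they ranged from 2 to 241, from 2 to 185 and from 0 to 56, and lists past the threshold from 12 to 19. List counts were 12 under quantile normalization, 14 with slide as a fixed block and 0 with an estimated correlation. The fixed block and the first slide leave fewer arrays to estimate CCl4, the filters change the genes tested, and otherwise the cause was not tested.

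The replicate number as a block gave 10 changed genes (10 higher, 0 lower), 9 of them shared, and 18 lists, without macrophage markers (adjusted p = 0.0782) and heat shock genes (adjusted p = 0.0736) and with the conjugating enzymes (adjusted p = 0.0491). Same-numbered arrays correlated at -0.052, 0.162 and 0.019 in their deviations, so the numbers were not taken to pair the animals.

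The direction of the test turned for some lists that had not passed, and the cause was not tested. With an array left out, list medians ranged from -0.046 to 0.069 for lymphocytes (test turned without corn oil replicate 2, at 0.038), from -0.169 to 0.001 for neutrophils (without CCl4 replicate 1, at 0.001, and corn oil replicate 2, at -0.041), from -0.046 to 0.170 for endothelium (without CCl4 replicate 3, at -0.046), from -0.210 to 0.455 for erythroid genes (without CCl4 replicate 3, at -0.210), from -0.014 to 0.279 for endoplasmic reticulum stress (without corn oil replicate 1, at -0.014) and from -0.530 to -0.173 for female-predominant genes (without corn oil replicate 1, at -0.207). The test also turned for neutrophils without a filter (0.004), for other tissues on all 6 arrays (-0.029) and for endothelium with slide as a block or within the first slide (-0.158). Medians near 0 changed sign in further settings while the test kept its direction, among them those of lymphocytes (0.069 without corn oil replicate 1, 0.009 without CCl4 replicate 1, 0.044 without CCl4 replicate 3), erythroid genes (0.305 without corn oil replicate 2, 0.455 without CCl4 replicate 2) and the macrophage list, which had passed (-0.039 without corn oil replicate 1). Of genes that had not passed, with an array left out Col1a1 ranged from -0.074 (without CCl4 replicate 1) to 0.436 and Glul from -0.454 to 0.008 (without CCl4 replicate 3). Col1a1 was at 0.628 with slide as a block and 1.091 with probe means. Cdkn1a was at 0.229 with probe means, and with slide as a block or within the first slide Cd68 was at -0.018, Acta2 at 0.021 and Nqo1 at 0.004. List tests were not run with the random block, trend or array weights. Probes near background limit the least abundant genes, and 8 genes that rose have only a bound.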

Other observations

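Of the 76 changed genes 61 were in none of the 29 lists, and the groups named here were formed after their values were seen, without an enrichment test. Several rose that are known from leukocytes: the C-type lectin genes Clec12a (1.15 ± 0.13, adjusted p = 0.0252) and Clec4a2 (1.20 ± 0.13, adjusted p = 0.0252), the survival gene Bcl2a1 (1.18 ± 0.15, adjusted p = 0.0340) and the adaptor gene Blnk (1.34 ± 0.14, adjusted p = 0.0252). Clec7a, a receptor for fungal glucans, was not well above background on any corn oil array and was at least 4.27-fold higher (adjusted p = 0.0298). Lipid genes also rose: Fabp4, a fatty acid binding protein of adipocytes and macrophages, by 4.09 ± 0.35 (adjusted p = 0.0171), Pla2g7, a phospholipase of macrophages, by 2.59 ± 0.14 (adjusted p = 0.00383), and Lpl, which releases fatty acids from lipoproteins, by 1.56 ± 0.17 (adjusted p = 0.0252). Fabp4 was well above background on 2 of 3 corn oil arrays. The mitotic genes Pkmyt1 (2.03 ± 0.23, adjusted p = 0.0256) and Kif18b (1.38 ± 0.18, adjusted p = 0.0368), outside the cell cycle list, rose as well, and Ska1 was at least 3.01-fold higher (adjusted p = 0.0252).

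Lcn2, an acute phase and neutrophil gene, split the CCl4 arrays by slide: it lay at -3.11 in CCl4 replicate 1 and at 2.40 and 1.99 in CCl4 replicates 2 and 3, against -2.04, -0.96 and -1.38 in corn oil (log2 relative to each array's 75th percentile; adjusted p = 0.494).

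The rises of Trem2, Gpnmb and Lgals3 led to the hypothesis that a lipid-associated macrophage state may be more common in CCl4 livers, for which 19 other genes of that state were listed before their values were seen. Their median change was 0.16, with 13 positive, and limma's camera test gave 0.0259 at its preset correlation but 0.0727 with an estimated one. None passed over all genes, and Lgals1 alone (1.13 ± 0.23) passed over the list, at an adjusted p = 0.0446. The result is consistent with the hypothesis only at the preset correlation. All 19 genes were well above background on the 3 corn oil arrays, so the liver expresses them without CCl4, and whole tissue does not tell which cells changed.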
